A study of Saccharomyces cerevisiae with 16 samples.

How the data were processed

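The series measured polyadenylated RNA of the budding yeast Saccharomyces cerevisiae, strain BY4741, with 3′T-fill, a sequencing method that reads the end of a transcript at its poly(A) tail. BY4741 is a haploid laboratory strain of mating type a with mutations in his3, leu2, ura3 and met15. Single cells were enclosed in alginate particles and grew in them into microcolonies in rich medium at 30 °C. The labels give 16 libraries: 3 of fixed unsorted particles, 3 of fixed big colonies, 4 of fixed small colonies, 2 of unsorted particles that were not fixed with ethanol, and 2 each of batch cultures without particles at Abs600 0.5 and 2. Big and small colonies were sorted by size in a flow cytometer for large particles after ethanol fixation, per the labels' protocols, which give 500 to 3000 ng of total RNA as input. The series design calls the libraries of a group biological replicates. It does not say how the cultures or days were shared between groups.

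The deposited table holds raw counts of 3′ end tags at 542908 stranded genome positions, 1 column per library, with no normalization. The submitters' processing notes name CASAVA 1.8.2 and GSNAP and the genome builds R64 and sacCer3, and the role of each is not given in the sources used here. How positions were filtered and whether duplicate reads were removed is not stated either. A further column, the authors' total, equalled the sum of the 16 library counts at each of the 542908 positions and was not used. No molecular identifiers are described, so intervals and lower bounds below cover counting error only.

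Columns were tied to samples by the title and barcode in the column name. The column of small replicate 4 was tied by the replicate number in its name. That library was barcoded in a separate index read, while the other 15 carry the barcode in the second read. Its title and description call it a fixed small colony sample, but its sample type label reads as unfixed, and it was grouped by the title. Small replicates 1 and 3 were left out of the main tests because the submitters excluded them for low quality. Those 2 libraries held 11821 and 839550 tags.

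The strand of the table was compared with the annotation at 2448 isolated genes. Tags lay on the strand opposite to the one given in the table, so the strand was turned. After turning, 92.7% to 98.5% of the tags near those genes lay on the transcript strand in the 14 libraries tested. A tag was counted for 1 of 6002 annotated protein-coding genes when it lay on the transcript strand in the ORF, or within 400 nt after it and before the next gene on that strand. Gene positions come from the RefSeq annotation of the R64 build. These gene counts held 88.8% to 96.3% of the tags of a library. Tags of other gene types took 0.392% to 2.56%, tags at no gene 2.90% to 10.6%, and tags in 2 overlapping genes at most 0.0257%. Genes with near-identical copies can share or lose tags in alignment, and their values are less certain.

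Gene counts were tested with the edgeR 4.0.16 quasi-likelihood test with robust estimation, TMM scaling and filterByExpr, in 1 fit of 14 libraries in 6 groups, with Benjamini-Hochberg adjustment and a threshold of 0.05. The filter left 5528 genes, and the fit had 8 residual degrees of freedom. Standard errors of log2 fold changes were computed as the size of the log2 fold change divided by the square root of the F statistic. CPM values are gene tags scaled to a common library size with the TMM factors. Of 38 gene lists written before the data were examined, the 33 with at least 5 tested genes were compared with the other genes by camera with a preset correlation of 0.01 on log2 CPM with a prior count of 2, in limma 3.58.1. Camera with an estimated correlation and fry, in 1 direction and with changes both ways counted, were run beside it. A list's median is that of the edgeR log2 fold changes; with a library left out it is that of differences of mean log2 CPM, and the text gives the full value on the same scale. The 3′ end position of a gene was the mean distance of its tags from the end of the ORF, positive after it. Positions were tested with limma for 1759 genes with at least 50 tags in each of the 14 libraries, weighted by tags up to 200. Software was R 4.3.3, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

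The 6 gene comparisons, the 4 position comparisons, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule takes up to 10 genes per direction with the largest log2 fold change among genes past the threshold, with a mean of at least 5 CPM and no overlap between the libraries of the 2 groups. It adds up to 4 members per list past the threshold, or 2 in the comparisons with fixed unsorted particles, along with the strain's marker genes and reference genes. For positions it takes up to 3 genes per direction with at least 100 tags in each library. The text describes a selection of the genes under this rule. Lower bounds on folds are computed against 3 counts over all libraries of the group with no tags.

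Alternatives were DESeq2 size factors in the same test, no filter and a filter of 5 CPM in 2 libraries, DESeq2, limma-voom, the libraries of the 2 groups alone, thinning to the smallest library, genes with a standard name, a window of 200 nt, the excluded libraries added, the other batch density as control, a replicate block, and each library left out in turn. After the data were seen, the comparison of fixed unsorted particles with batch culture was added, along with the fit without the small libraries, voom with sample quality weights, only positions after the ORF, and the choice of genes in 1 pair of libraries to be read in the other.

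The steps were tested on simulated counts with 100 genes changed 2-fold and 100 changed 8-fold in each comparison. Each gene was drawn with 1 dispersion in all groups, estimated over the 14 libraries. The 2 small libraries differed most among replicate pairs, with a chi-square per degree of freedom of 420. The counts below therefore need not hold where real groups differ in spread, above all for small colonies. For small against big colonies, run on 5476 genes, 0 of the 2-fold and 36 of the 8-fold changes were recovered with 2 false calls. For big colonies against unsorted particles, on 5469 genes, 0 and 52 were recovered with 2 false calls. The counts were 1 and 36 with 1 false call for small colonies against unsorted particles, on 5473 genes. They were 0 and 31 with 3 false calls for fixed against unfixed particles, on 5478 genes. For unfixed particles against batch culture, on 5467 genes, 0 and 16 were recovered with 1 false call, and for the 2 batch densities, on 5472 genes, 1 and 21 with 2 false calls. On simulated lists for unfixed particles against batch culture the list test called the 1 list that was moved and 0 of the others. The position test, simulated for the same comparison on 1759 genes, found 58 of 100 genes moved by 100 nt, with 2 false calls.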

Results

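Transcript 3′ ends were counted in microcolonies that had grown from single yeast cells enclosed in alginate particles, and in the same strain grown in batch culture. The 14 libraries compared were 3 of fixed unsorted particles, 3 of sorted big colonies, 2 of sorted small colonies, 2 of unsorted particles without ethanol fixation, and 2 at each of 2 batch densities, Abs600 0.5 and 2. Library totals ranged from 1506960 tags for unsorted replicate 2 to 7871184 for small replicate 4. Small replicate 2 held 1873907 tags, big colonies 3103727 to 4261351, fixed unsorted particles up to 4750543, unfixed particles 2247522 and 2277047, the batch cultures at Abs600 0.5 1665301 and 2312361, and those at Abs600 2 3224323 and 3552293. The replicate pairs of a group differed by far more than counting error, with a chi-square per degree of freedom of 25.6 to 420 over 10 pairs, so none was merged with another as the same library. This does not show that the libraries are independent.

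The 2 small-colony libraries and the 2 unfixed libraries lay apart from the other 10. The correlation of log2 CPM between the 2 small libraries was 0.529, against 0.893 to 0.945 within big colonies and 0.886 to 0.942 within fixed unsorted particles. With big colonies it was higher, at 0.742 to 0.77 for small replicate 2 and 0.622 to 0.676 for small replicate 4. It was 0.867 between the 2 unfixed libraries and 0.711 to 0.832 between them and the other groups apart from the small colonies. Small replicate 2 had tags on 28602 positions and 4403 genes, against 84020 to 156348 positions and 5412 to 5623 genes in the 10 libraries of the other groups, unfixed libraries left out. In small replicate 4 the base at the 3′ end was C for 31.9% and G for 24.3% of gene tags, against 14.4% to 16.3% and 39.8% to 47.5% in the 13 other libraries. The strain's markers were read where the tags allow it. MET17 (MET15), deleted in BY4741, had 0 tags in 13 libraries and 3 in small replicate 4. URA3 had 1 to 84 tags in each of the 14 libraries, and all 645 lay after the ORF. HIS3 had 327 to 2458, of which 8 in all lay inside the ORF. LEU2 had 519 tags in small replicate 4, all after the ORF, against 0 to 7 elsewhere. Tags outside the deleted part of a marker check nothing. The reference gene ACT1 passed the threshold in no comparison, with 8327 ± 1755 CPM (SD, n = 2) in batch culture at Abs600 0.5 and 11980 ± 623 CPM (SD, n = 2) in unfixed particles.

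**Figure D1:**
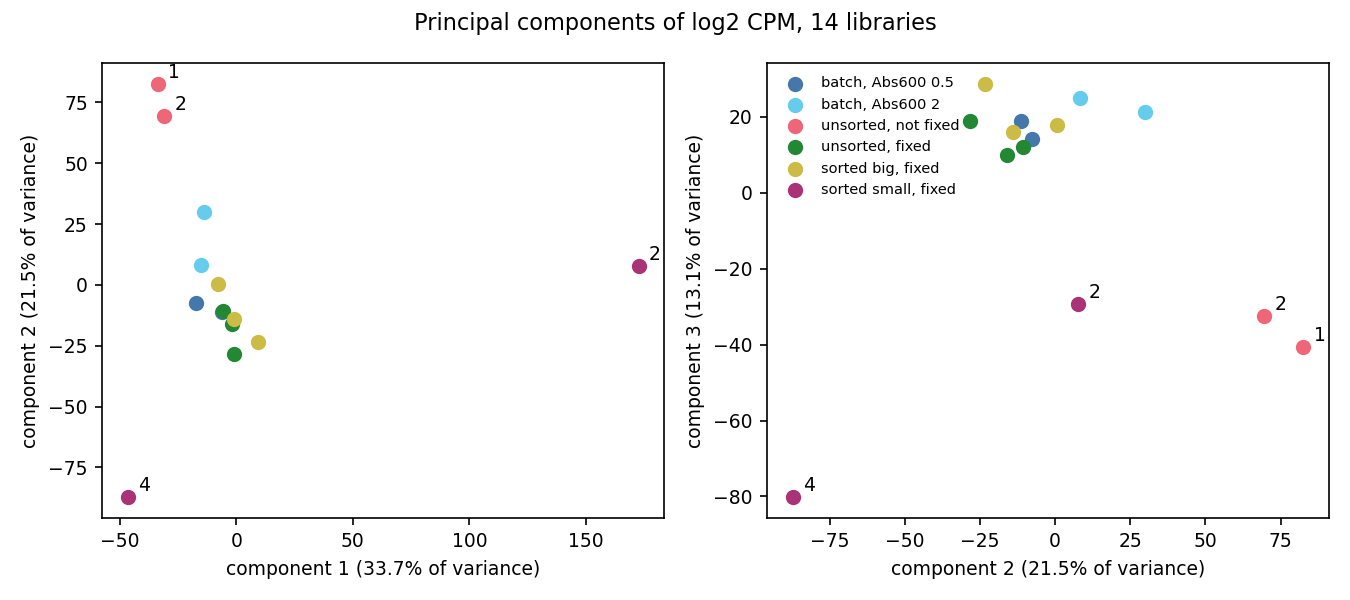
Principal components of log2 CPM for 14 libraries, 1 point per library, coloured by group, with components 1 and 2 on the left and 2 and 3 on the right; axes are component scores with the percent of variance (33.7, 21.5 and 13.1). Numbers beside points are replicate numbers of the small and unfixed libraries, which lie away from the other 10 points.

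Unfixed microcolonies were compared with batch culture at Abs600 0.5, a control for growth inside the particles. Past the threshold, 19 of 59 genes of the general stress response were higher in the unfixed particles, and 19 of 83 genes of ribosome biogenesis and 4 of 10 histone genes were lower. The calls of the last 2 lists were lost with an estimated correlation (adjusted p = 0.0923 and 0.223). RTC3 (YHR087W, chromosome VIII, 280820 to 281155 in R64), a stress-induced gene, was at 920.4 ± 2.31 CPM (SD, n = 2) against 7.75 ± 4.99 (SD, n = 2), a log2 fold change of 6.86 with SE 0.87 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00377). CTT1 (YGR088W, chromosome VII, 654634 to 656322), the cytosolic catalase, was at 1195 ± 10.03 against 14.7 ± 8.10 CPM (SD, n = 2 each), log2 6.36 with SE 1.06. ENP1 (YBR247C, chromosome II, 713004 to 714455), needed for small ribosomal subunit assembly, fell to 2.47 ± 1.56 from 166 ± 84.2 CPM (SD, n = 2 each), log2 -6.05 with SE 0.91. The low-affinity glucose transporter gene HXT3 (YDR345C, chromosome IV, 1162957 to 1164660) fell to 11.5 ± 2.09 from 346 ± 105 CPM (SD, n = 2 each), log2 -4.91 with SE 0.87.

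Of 59 stress-induced genes tested, 19 rose past the threshold over all genes, 0 fell and 40 did not pass, with 46 rising when adjusted over the list alone. The list's median log2 fold change was 4.16, or 4.13 with genes that had no tags in 1 group set at their bound, and its call held with an estimated correlation (adjusted p = 0.0315). Other members were PGM2, phosphoglucomutase, at log2 5.83 (SE 0.98), and SOL4, of the pentose phosphate pathway, at 6.001 (SE 1.02). HSP12, encoding a membrane-associated stress protein, was at 378 ± 75.8 CPM against 0.939 ± 1.33, and the mitochondrial pyruvate carrier gene MPC3 at 125 ± 16.5 against 0.586 ± 0.165 CPM (SD, n = 2 each). The log2 fold change of HSP12, 8.43, ranged from 2.90 to 13.3 over the alternatives, the highest without batch replicate 1. ZNF1, a transcription factor gene of respiratory growth, had no tags in the batch cultures and was at least 141-fold higher in unfixed particles. Among 28 heat shock and chaperone genes 1 rose, HSP42, encoding a small heat shock protein, at log2 5.43 (SE 0.96), with 2 adjusted over the list alone and a median of 0.53 (adjusted p = 0.637 with an estimated correlation). That list's call was lost without unfixed replicate 2 or batch replicate 2. Over the alternatives the log2 fold change of HSP42 ranged from 1.95 to 5.97. Of 18 genes of the osmotic stress response, 2 rose, the aldehyde dehydrogenase gene ALD3 at 4.44 (SE 0.96) and GRE2 at 3.68 (SE 0.72), with 8 adjusted over the list alone and a median of 2.05 (adjusted p = 0.223 with an estimated correlation). Of 25 genes of hypoxia and sterol uptake, 1 rose, the carbonic anhydrase gene NCE103 at 4.14 (SE 0.91), with 5 adjusted over the list alone and a median of 0.85 (adjusted p = 0.483 with an estimated correlation). The hypoxia median from mean log2 CPM was 0.86, and 0.44 without batch replicate 1. Without unfixed replicate 1 it was 0.425 and the call was lost.

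Of 83 ribosome biogenesis genes, 19 fell and 0 rose, with 66 falling when adjusted over the list alone; the median was -2.39 and all 83 values were negative (adjusted p = 0.0923 with an estimated correlation). PWP1, MAK5 and ENP2, of ribosomal subunit assembly, were at log2 -3.70 (SE 0.61), -4.07 (SE 0.68) and -2.77 (SE 0.54), and RPA49, an RNA polymerase I subunit, was at -5.53 (SE 1.08). Of 132 ribosomal protein genes, 0 passed singly or over the list alone; the list's median was -1.19 (adjusted p = 0.34 with an estimated correlation). Of 10 histone genes 4 fell, with 8 adjusted over the list alone and a median of -2.83 (adjusted p = 0.223 with an estimated correlation). HTB2, HTA2 and HHF1 were at log2 -3.08 (SE 0.58), -3.27 (SE 0.70) and -3.49 (SE 0.76). HHT2 fell by 2.57 (SE 0.51), but its log2 fold change was 0.44 with a window of 200 nt after the ORF. Single genes of other lists that fell were MFA2, an a-factor gene (log2 -4.46, SE 0.84), IZH1 of the zinc regulon (-4.43, SE 0.98), PHO3, an acid phosphatase gene repressed by thiamine (-2.60, SE 0.54), GIC2 of bud emergence (-2.13, SE 0.52) and, outside the lists, the adenine deaminase gene AAH1 (-5.01, SE 0.77). The share of antisense tags was 5.12% and 4.17% in the unfixed libraries against 1.49% and 1.62% in these batch cultures. The camera test called 12 of 33 lists, 7 up and 5 down, of which 1 held with an estimated correlation. Fry, which does not compare a list with other genes, called 4 in 1 direction and 10 with changes both ways counted.

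In all, 42 genes rose and 65 fell among the 5528 tested. The count of 107 was 1 without unfixed replicate 1, 28 without unfixed replicate 2, 16 without batch replicate 1 and 2 without batch replicate 2, and 41 against batch culture at Abs600 2 as the control. It was 402 with DESeq2, 988 from the 4 libraries alone, 916 with a replicate block and, in alternatives chosen after seeing the data, 677 (293 higher, 384 lower) without the small libraries in the fit and 1030 by voom with sample quality weights. More genes rose than fell by limma-voom (54 and 23), from the 4 libraries alone (514 and 474), with a replicate block (459 and 457) and with quality weights (546 and 484).

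**Figure D2:**
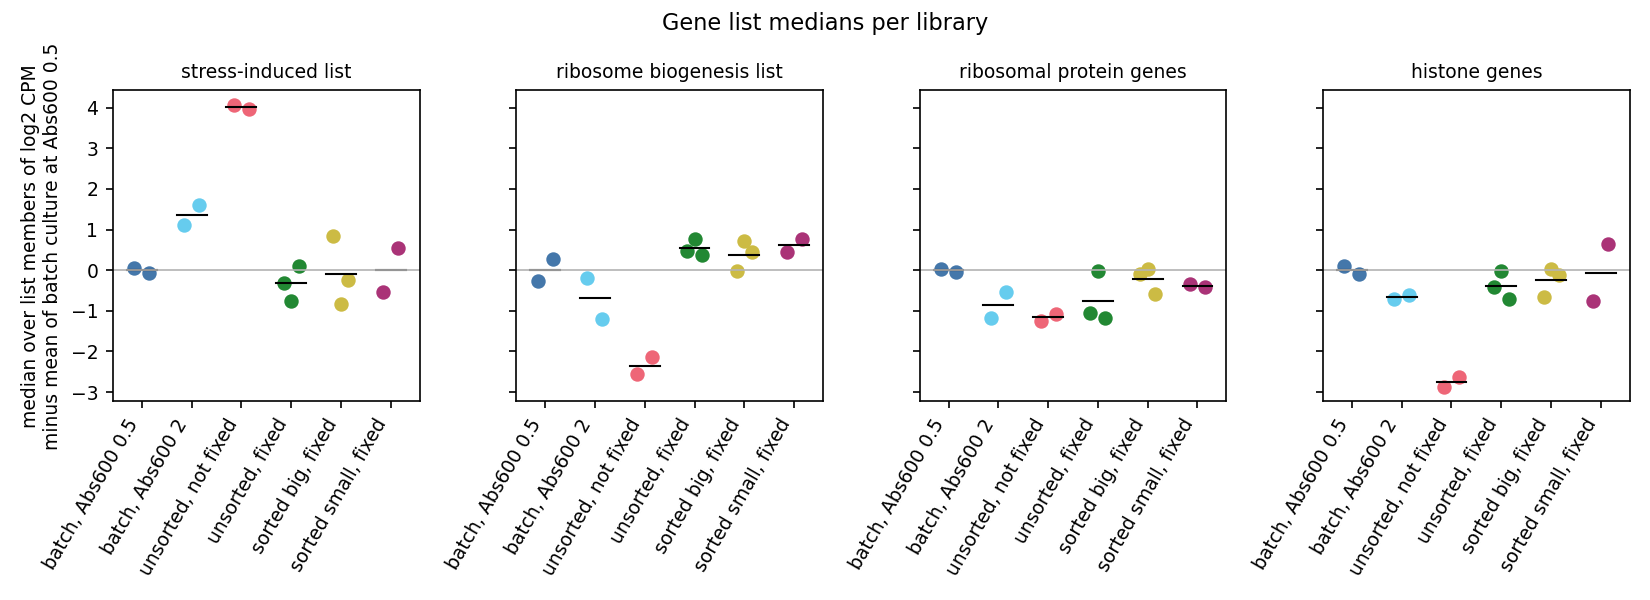
Median over a gene list of log2 CPM minus the mean of the batch cultures at Abs600 0.5 (y axis, log2 units), 1 point per library and a line at the mean of each group on the x axis, for 4 lists. The 2 unfixed libraries lie at 4.08 and 3.96 for the stress-induced list, above every other library, and at -2.55 and -2.15 for ribosome biogenesis, below every other library.

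Fixed unsorted particles were compared with unfixed ones, a control for ethanol fixation. The 2 unfixed libraries are those compared with batch culture above, so opposite changes here are not an independent second result. Past the threshold, 56 of 83 ribosome biogenesis genes and 6 of 10 histone genes were higher in the fixed particles, and 38 of 59 stress-induced genes lower. The histone list's call was lost with an estimated correlation (adjusted p = 0.352). RTC3 was at 2.86 ± 0.8504 CPM (SD, n = 3) against 920.4 ± 2.31 (SD, n = 2), log2 -8.32 with SE 0.78 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 6.96e-05). GPH1, glycogen phosphorylase, was at 10.7 ± 1.69 (SD, n = 3) against 2245 ± 458 CPM (SD, n = 2), log2 -7.72 with SE 0.88. HXK1, a hexokinase gene repressed by glucose, fell by 7.74 (SE 0.95), from 1997 ± 53.0 (SD, n = 2) to 9.29 ± 3.38 CPM (SD, n = 3). ENP1 rose by 5.85 (SE 0.88) and AAH1 by 5.52 (SE 0.77).

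Of 83 ribosome biogenesis genes 56 rose and 0 fell, with 75 rising when adjusted over the list alone and a median of 2.86 (adjusted p = 0.0456 with an estimated correlation); PWP1 rose by 4.37 (SE 0.61) and MAK5 by 4.45 (SE 0.67). Of 59 stress-induced genes 38 fell and 0 rose, with 49 falling when adjusted over the list alone and a median of -4.04 (adjusted p = 0.0331 with an estimated correlation). Of 10 histone genes 6 rose, with 7 adjusted over the list alone and a median of 2.59 (adjusted p = 0.352 with an estimated correlation), among them HTB2 (log2 2.54, SE 0.54) and HHT2 (2.32, SE 0.49), the latter at -0.68 with a window of 200 nt. Of 18 osmotic stress genes 8 fell, the same number over the list alone, with a median of -2.56 (adjusted p = 0.305 with an estimated correlation); the glycerol phosphatase gene GPP2 was at -5.98 (SE 0.90) and ALD3 at -4.601 (SE 0.82). Of 25 hypoxia and sterol uptake genes 2 fell, COX5B (log2 -4.25, SE 0.51) and CYC7 (-5.52, SE 1.24), which encode the hypoxic forms of a cytochrome c oxidase subunit and of cytochrome c; the list did not pass (adjusted p = 0.0935). COX5A, the form used in air, rose by 2.96 (SE 0.71). Of 27 oxidative stress genes 4 fell, with 5 over the list alone, and the list did not pass (adjusted p = 0.0822); PRX1, a mitochondrial peroxiredoxin gene, fell by 4.90 (SE 1.11). Of 28 heat shock and chaperone genes 4 fell, with 6 falling and 1 rising over the list alone and a median of -0.05 (adjusted p = 0.783 with an estimated correlation), among them HSP42 (-3.11, SE 0.73) and SSA1 (-2.40, SE 0.51). From mean log2 CPM the heat shock median was -0.38, and -0.68 and -0.72 without unfixed replicate 1 and unsorted replicate 1. The call was lost without unfixed replicate 2 (-0.23) and without unsorted replicate 2, where the median was 0.13.

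In other lists, HXT3 rose by 5.05 (SE 0.86), MFA2 by 3.15 (SE 0.77), and the zinc regulon genes IZH1 and IZH2 by 5.24 (SE 0.98) and 3.08 (SE 0.73). ALD4, mitochondrial aldehyde dehydrogenase, fell by 3.95 (SE 0.83) and CIT1, citrate synthase, fell by 2.64 (SE 0.71), the only one of 13 citric acid cycle genes past the threshold (list median -1.32, adjusted p = 0.404 with an estimated correlation). Of 32 cell wall genes 1 fell and 1 rose, CWP1 at log2 -3.58 (SE 0.66) and TIP1 at 3.26 (SE 0.77), or 4.92 without unfixed replicate 2, both mannoprotein genes (list adjusted p = 0.862). ENA1, a sodium pump gene, had no tags in the fixed particles and was at least 100-fold lower there. PUF3, an RNA-binding protein gene, had none in the unfixed ones and was at least 19.5-fold higher in the fixed, or 10.7-fold without unsorted replicate 2. The camera test called 11 of 33 lists, 3 up and 8 down, of which 2 held with an estimated correlation. Fry called 4 in 1 direction and 11 both ways. In total 187 genes rose and 136 fell. The count of 323 was 36 and 106 without unfixed replicates 1 and 2, 152, 148 and 190 without unsorted replicates 1, 2 and 3, 647 with DESeq2, 834 from the 5 libraries alone and 624 with a replicate block of 4 libraries. In alternatives chosen after seeing the data it was 1093 without the small libraries in the fit and 1095 by voom with sample quality weights. More genes fell than rose by limma-voom (192 and 144), from the 5 libraries alone (431 and 403), with a replicate block (319 and 305), with quality weights (619 and 476) and without unfixed replicate 1 (25 and 11).

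Small and big colonies were compared because the size of a microcolony follows the growth of its founder cell. SML1 (YML058W, chromosome XIII, 159383 to 159697), an inhibitor of ribonucleotide reductase, was at 265 ± 27.4 CPM in small (SD, n = 2) against 34.8 ± 0.649 in big colonies (SD, n = 3), log2 2.93 with SE 0.50 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0253). With a window of 200 nt after the ORF it was at 0.86 and did not pass. HSP31 (YDR533C, chromosome IV, 1501447 to 1502160), a methylglyoxalase and chaperone gene, was at 4.62 ± 2.88 (SD, n = 2) against 63.3 ± 16.1 CPM (SD, n = 3), log2 -3.66 with SE 0.58. MST28 (YAR033W, chromosome I, 188107 to 188811), a membrane protein gene with a close paralog, was at 2.53 ± 1.76 (SD, n = 2) against 65.99 ± 12.4 CPM (SD, n = 3), log2 -4.52 with SE 0.74.

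In all, 31 genes were higher and 39 lower in small colonies, whose 2 libraries were less alike than each was to big colonies. Higher were SSA4, a heat-induced chaperone gene (log2 2.86, SE 0.60), ATP1 of the mitochondrial ATP synthase (4.06, SE 0.80), PGK1 of glycolysis (3.10, SE 0.61), OLE1, the fatty acid desaturase gene (3.85, SE 0.84), and ILV1 of isoleucine synthesis (3.31, SE 0.76). MFA2 was higher by 3.04 (SE 0.65). The level of PGK1 in small colonies was 1068 ± 993.5, of OLE1 590.4 ± 659, of ILV1 128 ± 115 and of MFA2 504 ± 496 CPM (SD, n = 2), with the higher value in replicate 4. Without replicate 4 PGK1 was at log2 1.55, and OLE1, ILV1 and MFA2, at 1.60, 1.84 and 1.33, did not pass. EGO4 was higher by 4.10 (SE 0.84), the splicing factor gene PRP39 by 4.14 (SE 0.92), PUF3 by 4.32 (SE 0.98), the cyclin gene PCL5 by 4.79 (SE 1.02) and the phosphatase gene PPQ1 by 3.97 (SE 0.89). FIG1, a mating gene, had no tags in big colonies and was at least 220-fold higher in small ones, or 34.7-fold without small replicate 4 and 406-fold without replicate 2. Lower were the mitochondrial ribosomal protein genes MRPL24 (log2 -3.26, SE 0.71) and MRPL35 (-3.15, SE 0.60), the mitochondrial seryl-tRNA synthetase gene DIA4 (-3.84, SE 0.79), the isocitrate dehydrogenase gene IDP2 (-3.04, SE 0.57), SHR5 of protein palmitoylation (-3.49, SE 0.77), the daughter-cell gene DSE3 (-2.38, SE 0.56), CVM1 (-3.96, SE 0.92) and DMO1 (-4.86, SE 0.89). Without small replicate 4, MRPL24 was at -5.298 and DIA4 at -6.15. CVM1 and DMO1 had no tags in small replicate 2. The kinetochore gene CTF19 had no tags in small colonies and was at least 44.4-fold lower there, or 23.0-fold without big replicate 1.

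No list of 33 passed between small and big colonies with the camera test at either correlation, nor with fry in 1 direction. Fry with changes both ways counted called 1, the mating genes (adjusted p = 1.19e-05). The camera count was 2 without big replicate 2. Of 59 stress-induced genes 1 rose (SSA4) and 1 fell (HSP31), the same over the list alone. Of 67 mitochondrial ribosome genes 0 rose and 2 fell, with 1 and 2 over the list alone. Of 19 mating genes 2 rose and 0 fell, with 3 and 1 over the list alone. Of the tested genes of the other mating type, SAG1, MF(ALPHA)2 and MF(ALPHA)1 had positive log2 fold changes and AFB1 a negative one. None passed. MF(ALPHA)2 was at 3.71 (SE 2.40) and MF(ALPHA)1 at 1.42 (SE 2.03), both with no tags in small replicate 2. SAG1, the alpha-agglutinin gene, was at 50.2 ± 42.3 CPM (SD, n = 2) against 3.64 ± 3.29 in big colonies (SD, n = 3), log2 3.77 with SE 1.14 (adjusted p = 0.0955). Small replicate 4 held 41 tags of MATALPHA2, 115 of HMLALPHA2, 83 of STE3 and 137 of MF(ALPHA)1, all 4 with 0 tags in small replicate 2. MATALPHA2 and HMLALPHA2 can share tags with near-identical copies at the mating type loci, so their counts do not mark alpha cells. AFB1, an a-factor barrier gene of alpha cells, was at 17.5 ± 3.76 against 34.2 ± 2.54 CPM, log2 -0.96 with SE 0.70 (adjusted p = 0.455). The median log2 fold change of all genes was 0.17, and DESeq2 size factors shifted it by 0.18 and gave 47 higher and 30 lower genes. The count of 70 was 0 without any 1 of big replicates 1, 2 and 3, 1671 without small replicate 2 and 1983 without small replicate 4, where the lone library is assumed to vary like the other groups. It was 0 with small replicates 1 and 3 added, with DMO1 and MRPL24 then at 2.03 and 0.34, and 0 from the 5 libraries alone, against 609 with DESeq2, 204 with limma-voom and, chosen after seeing the data, 755 by voom with sample quality weights. More genes were higher than lower with DESeq2 (389 and 220) and with quality weights (459 and 296). Small replicate 4 was barcoded in another way than every other library, so that library batch cannot be told apart from the group's share in it.

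Small colonies were also compared with fixed unsorted particles. The 2 small libraries are those compared with big colonies above, so the same changes here are not an independent second result. SML1 was higher by 2.78 (SE 0.50), at 265 ± 27.4 (SD, n = 2) against 38.7 ± 9.53 CPM (SD, n = 3), and at 1.79 without passing in a window of 200 nt (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.034 in the full window). EGO4 was higher by 5.52 (SE 0.91), VMA5, a vacuolar ATPase subunit gene, by 4.20 (SE 0.75), MFA2 by 3.45 (SE 0.66), or 1.73 without small replicate 4, PGK1 by 2.84 (SE 0.60), or 1.296 without it, and COR1 of respiratory complex III by 2.69 (SE 0.61). MST28 was lower, at log2 -4.79 (SE 0.75), as were the ubiquitin protease gene UBP5 at -3.15 (SE 0.54), HSP31 at -2.98 (SE 0.57), MRPL35 at -2.89 (SE 0.59), IDP2 at -2.44 (SE 0.56) and the calcineurin regulator gene RCN1 at -3.08 (SE 0.70). Over the alternatives the weakest values were -0.76 for UBP5, -1.16 for HSP31 and -0.79 for IDP2, against -2.26 for MRPL35 and -4.15 for MST28. CTF19 was at least 49.1-fold lower, or 23.2-fold without unsorted replicate 2. Of 132 ribosomal protein genes none passed singly; their median was 0.52 (adjusted p = 0.997 with an estimated correlation), and the list's call was lost without small replicate 2. From mean log2 CPM the median was 0.305, and 0.18, 0.73 and 0.14 without unsorted replicates 1, 2 and 3. Of 40 oxidative phosphorylation genes 1 rose, COR1, with 6 over the list alone and a median of 1.15 (adjusted p = 0.997 with an estimated correlation). On mean log2 CPM their median was 0.45, and -0.34 without small replicate 4 and 1.696 without replicate 2. Fry called 0 lists in 1 direction and, with changes both ways counted, the mating genes (adjusted p = 1.36e-05). These 2 lists were the ones called, against 1 without either small replicate and 4 without unsorted replicate 2. In all 20 genes were higher and 36 lower, against 24 and 17 with DESeq2 size factors, which shifted the median of all genes, 0.21, by 0.15. The count of 56 was 1 without unsorted replicate 1, 0 without replicate 2 or 3, 1433 without small replicate 2, 2111 without small replicate 4, 0 from the 5 libraries alone, 1 with small replicates 1 and 3, with RCN1 then at 0.98, 553 with DESeq2 (332 higher, 221 lower) and 130 with limma-voom.

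Big colonies were compared with fixed unsorted particles, and no single gene passed. The edgeR quasi-likelihood test called 0 of 5528 genes at an adjusted p of 0.05, with 51 genes at an unadjusted p under 0.05 where chance gives 276; DESeq2, limma-voom and voom with sample quality weights also called 0. With fewer genes than chance gives, the test was likely conservative here, and 0 calls do not show that nothing differed. The spread was shared with the small libraries, with a common dispersion of 0.395 with them and 0.198 without. The median standard error of a log2 fold change was 0.69. In counts simulated for this comparison, with 1 spread per gene shared by all groups, 0 of 100 2-fold and 52 of 100 8-fold changes were recovered. Some lists lay to 1 side. Of 132 ribosomal protein genes 117 had positive values, with a median log2 fold change of 0.44 in big colonies (camera adjusted p = 5.49e-28, and 0.49 with an estimated correlation). By mean log2 CPM their median was 0.54, and 0.95 and 0.31 without unsorted replicates 2 and 3. Of 40 genes for the use of other carbon sources, repressed by glucose, 36 were positive, with a median of 1.19 (adjusted p = 0.524 with an estimated correlation). Measured by mean log2 CPM it was 0.75, and 0.07 without big replicate 1 and 1.31 without big replicate 2. Of 40 oxidative phosphorylation genes 30 were positive, with a median of 0.45 (adjusted p = 0.524 with an estimated correlation), and of 19 mating genes 16, with a median of 0.45 (adjusted p = 0.453). As a difference of mean log2 CPM the mating median was 0.44, and 0.67 and 0.25 without unsorted replicates 2 and 3. Of 30 iron regulon genes 26 were negative, with a median of -0.68 (adjusted p = 0.453 with an estimated correlation). From mean log2 CPM it was -0.61, and -0.32 without unsorted replicate 1. The phosphate regulon was at -0.47 (adjusted p = 0.766 with an estimated correlation). On mean log2 CPM it was at -0.46, and at 0.13 without unsorted replicate 2, -0.87 without unsorted replicate 1, and -0.08 and -0.29, no longer called, without big replicates 1 and 2. None of the 8 lists called was called with an estimated correlation or by fry.

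The batch cultures at Abs600 2 and 0.5 were compared as a measure of what cell density does. No gene passed the edgeR quasi-likelihood test, with 191 genes at an unadjusted p under 0.05 where chance gives 276; limma-voom called 0, DESeq2 15 (10 higher, 5 lower), the 4 libraries alone 16, a replicate block 101 (58 higher, 43 lower), and voom with sample quality weights, chosen after seeing the data, 72. The edgeR count below chance again leaves the test likely conservative, so 0 calls do not show that density changes nothing. The stress-induced list had 55 of 59 values positive at Abs600 2, with a median of 1.61, or 1.58 with genes without tags at their bound, and 12 genes higher when adjusted over the list alone (adjusted p = 0.261 with an estimated correlation). Of 132 ribosomal protein genes 126 were negative, with a median of -0.81, and of 83 ribosome biogenesis genes 70, with a median of -0.69 (adjusted p = 0.378 for both with an estimated correlation); the second call was lost without the Abs600 2 replicate 2. By mean log2 CPM the first median was -0.87, and -0.53 without the Abs600 2 replicate 1. The second was -0.77, and -1.21 and -0.19 without the Abs600 2 replicates 1 and 2 and -0.47 without the Abs600 0.5 replicate 2. Oxidative phosphorylation genes had a median of 0.77 and mitochondrial ribosome genes one of 0.39 (adjusted p = 0.378 for both with an estimated correlation). The first was 0.74 from mean log2 CPM, and 0.43 without the Abs600 0.5 replicate 2. The 9 lists called became 5 without the Abs600 2 replicate 1, and 0 with an estimated correlation or by fry. Across 5528 genes, which are not independent replicates, the log2 fold changes of small against big colonies and of Abs600 2 against 0.5 had a Spearman correlation of -0.142, which was -0.187 without small replicate 2 and 0.004 without small replicate 4.

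The position of the 3′ end was compared in 1759 genes. In unfixed particles against batch culture at Abs600 0.5, the mean 3′ end lay nearer to the start of the gene at 73 genes and farther at 3 (limma, Benjamini-Hochberg adjusted p under 0.05). At URA2 (YJL130C, chromosome X, 165723 to 172367), of pyrimidine synthesis, it lay at -1230 ± 69.5 nt from the end of the ORF, that is inside it, against 11.8 ± 24.2 nt (SD, n = 2 each), a shift of -1240 nt with SE 135. At the amino acid permease gene GNP1 and the ribosome biogenesis gene DIP2 the shifts were -1600 (SE 114) and -1430 nt (SE 131). Shifts to later positions were small: 45.2 nt (SE 9.09) at SEC22, of vesicle transport, and 21.4 nt (SE 4.30) at RPS27B, a ribosomal protein gene. Fixed against unfixed particles gave the opposite, with 81 genes farther and 4 nearer, among them DIP2 at 1560 nt (SE 122) and URA2 at 1100 nt (SE 124). Both comparisons use the same 2 unfixed libraries, so the second is not independent of the first. Genes were also chosen by comparing 1 unfixed and 1 batch library and read in the other 2, a test chosen after seeing the data. The libraries of the other groups stayed in that fit and set its spread. At 104 genes chosen from replicates 2, 15.4% of tags lay inside the ORF in unfixed replicate 1 against 1.07% in batch replicate 1, and the mean 3′ end was nearer at 87. At 148 genes chosen from replicates 1, the shares in replicates 2 were 9.78% and 2.09%, and the end was nearer at 118. With only positions after the ORF, an alternative chosen after seeing the data, 1 and 7 genes were called in these comparisons. The 7 were 1 farther and 6 nearer, the reverse of the balance above, and 3 of them were among the 85. The counts of 76 and 85 were 0 and 0 with a replicate block of 4 libraries (smallest adjusted p = 0.569 and 0.518). They were 158 and 164 without unfixed replicate 1, 196 and 210 without unfixed replicate 2, and the first was 43 without batch replicate 1.

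Between small and big colonies 14 genes had later and 8 nearer 3′ ends. Among called genes with at least 100 tags in each library of the 2 groups, the largest shifts were at RPN1, a proteasome subunit gene, with 1570 nt (SE 223), and at REA1, a ribosome biogenesis gene, with -1510 nt (SE 197). BEM2, of cell polarity, moved by -1020 nt (SE 59.0). The mean at RPN1 lay inside the ORF in both groups, at -1010 ± 644 nt in small and -2580 ± 96.5 nt in big colonies (SD). At REA1 these were -1670 ± 615 and -169 ± 26.3 nt, and at BEM2 -955 ± 173 and 67.5 ± 48.9 nt. Such means weigh tags inside the ORF and do not show a moved transcript end. The count of 22 was 8, 10 and 10 without big replicates 1, 2 and 3, 541 and 192 without small replicates 2 and 4, and 59 with genes of at least 20 tags. With only positions after the ORF 59 genes had later and 7 nearer ends, and 5 of the 22 were among these 66. Between the batch densities 0 genes had later and 8 nearer ends, among them RPA190, the largest subunit of RNA polymerase I, with -306 nt (SE 23.5), and the tRNA synthetase gene HTS1 with -125 nt (SE 19.7). This count was 2 and 1 without Abs600 0.5 replicates 1 and 2, 108 without the Abs600 2 replicate 2, 0 with a replicate block (smallest adjusted p = 0.526), 14 with genes of at least 20 tags, and 5 with only positions after the ORF, of which 1 was among the 8, or with positions of at least 5 tags.

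**Figure D3:**
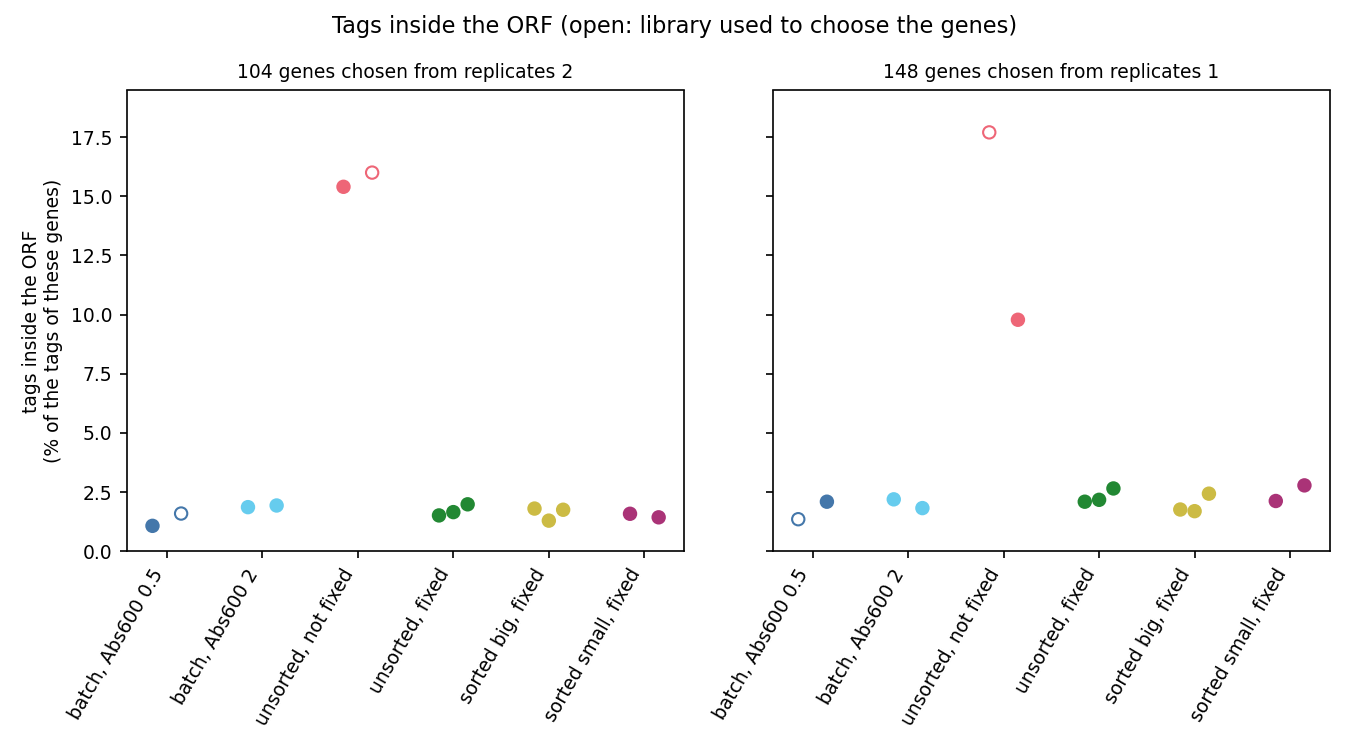
Tags inside the ORF as percent of the tags of a set of genes (y axis), 1 point per library by group on the x axis. The genes have nearer 3′ ends in 1 unfixed library than in 1 batch library, replicates 2 on the left (104 genes) and replicates 1 on the right (148 genes); open points are the libraries that chose them, and filled points were not used. The filled unfixed library lies at 15.4% on the left and 9.78% on the right, above all libraries of other groups, which lie at 1.07% to 1.98% and 1.35% to 2.78%.

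**Figure D4:**
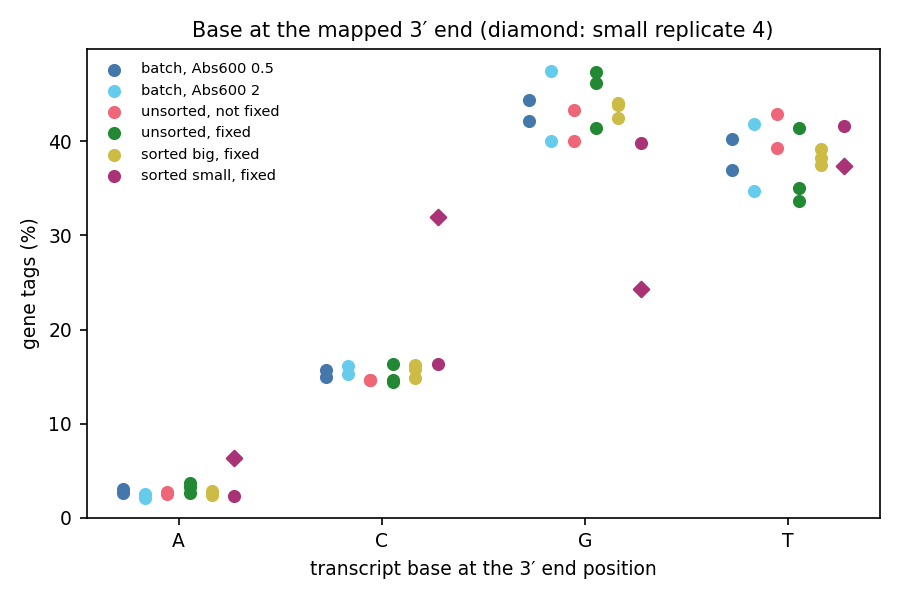
Percent of gene tags (y axis) by the transcript base at the 3′ end position (x axis), 1 point per library, coloured by group, with small replicate 4 as a diamond. That library lies at 31.9% for C and 24.3% for G, outside the range of the other 13 libraries, 14.4% to 16.3% and 39.8% to 47.5%.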

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

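Tests chosen only after the result was seen were that of growth inside the particles and the 4 tests on tags inside the ORF, on the same tags at genes called from other libraries, on loss of tags after the ORF and on A-rich stretches, along with the fit on positions after the ORF.

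Antisense tags were outside the comparisons and stood out because they exceeded 2.0 times the highest batch library, at 1.82% of the tags at isolated genes. They made up 5.12% in unfixed replicate 1, 4.17% in unfixed replicate 2, 7.35% in small replicate 4, and 6.25% and 4.90% in the excluded small replicates 1 and 3.

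The first pattern is the higher stress-induced and lower ribosome biogenesis genes in unfixed particles, with list medians of 4.16 and -2.39 against batch culture. Tags away from transcript ends do not account for it, since tags after the ORF alone gave a stress median of 4.17, and neither does a scale set by a few abundant genes, since DESeq2 size factors gave 4.25 and -2.29. Growth inside the particles alone would leave fixed unsorted particles as far from batch culture, but their stress median was -0.42 (quartiles -0.996 and 0.60), with 5 of 59 genes over log2 2 against 52 in unfixed particles. What happened to living cells between harvest and RNA extraction without fixation may be behind it, which was not tested.

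The second pattern is that the 2 small libraries lie apart from each other and from the rest. A preference of small replicate 4 for certain last bases does not account for it alone, since within positions ending in 1 base its mean correlation with big libraries reached 0.668, against 0.895 within big colonies at the same base. Handling like the unfixed cells, which its sample type label names, would raise the stress list if it acted as in the unfixed group. The stress median against the mean of big colonies was 0.49 (quartiles -0.75 and 2.15) and that of ribosome biogenesis 0.42. In small replicate 2 they were -0.99 and 0.008, and in the unfixed group 3.95 and -2.79. But small replicate 4 had 7.35% antisense tags, against 5.12% and 4.17% in that group and 1.49% to 2.15% in the 10 libraries of other groups. Excluded small replicates 1 and 3 had 6.25% and 4.90%. Whether small replicate 4 was fixed therefore stays open. Lower depth of small replicate 2 does not account for its 4403 genes, since big libraries thinned to its total kept tags on at least 5300. Few RNA molecules behind replicate 2 cannot be told apart from a difference of the sorted cells, since big libraries reduced to so few molecules correlated at 0.829 with the other big libraries on average, against 0.761 for replicate 2, and the reduction was simulated; the library batch of replicate 4 and the growth of small colonies stay open too.

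The third pattern is the nearer mean 3′ ends at 73 genes in unfixed particles. The calls rest on tags inside the ORF, since without those positions 1 of the 76 genes called nearer or farther was left. Genes called for this shift must show it in the libraries that called them. Genes were therefore also called by comparing 1 unfixed and 1 batch library, with the other groups kept in the fit, and read in the other 2. Tags inside the ORF were then at a median log2 ratio of 2.78 (quartiles 0.17 and 4.62) and 1.699 (quartiles -0.65 and 3.67), and the second spread reaches below 0, so a rise at all such genes cannot be told apart from one at part of them. A replicate block of 4 libraries gave 0 calls. Loss of tags after the ORF does not account for the shift alone. In the pairs left out of the calls, tags after the ORF were at medians of -0.70 and -0.58, beside 2.78 and 1.699 inside it. At the 73 genes, which were called in these same libraries, tags after the ORF were at a median of -0.72 and tags inside it at 3.797. Priming at A-rich stretches alone would leave most of these tags before at least 6 A in 10 bases, but 25.5% were, or 27.0% and 23.5% per library, against 41.5% and 43.7% in batch culture at Abs600 0.5 and 30.3% and 25.9% at Abs600 2. The 73 genes were called in these libraries, so the shares cover tags at those genes only. Over all genes, 73.5% and 70.0% of tags inside the ORF preceded such stretches in unfixed replicates 1 and 2. In batch culture these shares were 88.5% and 92.2% at Abs600 0.5 and 91.2% and 79.4% at Abs600 2. Earlier polyadenylation and added tails on broken RNA may both give such tags, and neither was tested.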

How the results depend on the processing

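Alternatives chosen after seeing the data were the fit without the small libraries, voom with sample quality weights, only positions after the ORF, and all settings of fixed unsorted particles against batch culture. The cause of a change was not tested unless one is named. Where 1 library is left in a group, it is assumed to vary like the other groups.

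The 2 counts of small colonies moved most. Against big colonies (70) the count was 609 with DESeq2, 204 with limma-voom, 0 from the 5 libraries alone, 0 with small replicates 1 and 3, and 755 with quality weights, and it ranged from 0 to 1983 with 1 library left out. Against unsorted particles (56) these were 553, 130, 0, 1 and 686, with a range of 0 to 2111. Filters, thinning, scaling, the window and the ORF positions left both counts within 1.5 times, but the genes changed. Of the 70, 48 were called again with the 200 nt window, 50 with only positions after the ORF and 61 with DESeq2 size factors. Of the 56, these were 41, 35 and 37. Unfixed particles against batch culture (107) gave 402 with DESeq2, 988 from the 4 libraries alone, 41 with the other batch density, 677 without the small libraries and 1030 with quality weights, and 1 to 28 with 1 library left out. Fixed against unfixed particles (323) gave 647, 834, 1093 without the small libraries and 1095 with quality weights, and 36 to 190 with 1 library left out. The common dispersion was 0.395 with the small libraries and 0.198 without them. For the batch densities (0) the count was 15 with DESeq2, 16 from the 4 libraries alone and 72 with quality weights. For unsorted particles against batch culture (0) it was 1 with DESeq2 and 262 with quality weights. It stayed at 0 for big colonies against unsorted particles under all settings run. The real split of these 6 libraries into 3 and 3 gave 0 genes, so all 10 splits match it whatever they give and the number says nothing; the highest other count was 0, and 10 splits are too few for a share under 0.05.

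The numbers of the replicates gave no clear pairing of the libraries. Deviations of big and unsorted libraries of the same number correlated at -0.166, 0.029 and 0.188, and 1 of 3 big libraries correlated best with the unsorted library of its number. In the other comparisons without small colonies such correlations ran from -0.162 between the batch densities to 0.16 between unsorted particles and batch culture. They cannot show whether libraries shared a culture or a day. A replicate block gave 916 genes for unfixed particles against batch culture, 624 for fixed against unfixed, 101 for the batch densities, 0 for big colonies against unsorted particles, and 0 genes in each of 3 position comparisons. No paired analysis was possible for small colonies because they share 1 number with big colonies.

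For lists, the estimated correlation and fry left 0 and 0 of 8 for big colonies against unsorted particles, 1 and 4 of 12 for unfixed particles against batch culture, 0 and 0 of 2 for small colonies against unsorted particles, 2 and 4 of 11 for fixed against unfixed, 0 and 0 of 13 for unsorted particles against batch culture, and 0 and 0 of 9 for the batch densities. Positions after the ORF gave 5 of 9 for the batch densities and 1 for small against big colonies. With 1 library left out the list counts ranged from 0 to 2 for small against big colonies, 1 to 4 for small colonies against unsorted particles, 5 to 8 for the batch densities, 8 to 12 for big colonies against unsorted particles, 9 to 11 for unfixed particles against batch culture, 8 to 11 for fixed against unfixed and 11 to 15 for unsorted particles against batch culture. From mean log2 CPM the glucose-repressed list of big colonies (0.75) ranged over medians of 0.07 without big replicate 1, where the sign of its test reversed, to 1.31, and the phosphate list (-0.46) from -0.87 to 0.13 without unsorted replicate 2.

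For 3′ end positions, genes with at least 20 tags gave 59 for small against big colonies, 14 for the batch densities and 132 for fixed against unfixed. Positions with at least 5 tags gave 5 for the batch densities. Only positions after the ORF gave 66, 5, 7 and, for unfixed particles against batch culture, 1. That comparison gave 115 without the small libraries. With 1 library left out the ranges were 8 to 541 for small against big colonies, 43 to 196 for unfixed particles against batch culture, 64 to 210 for fixed against unfixed and 1 to 108 for the batch densities. The correlation of fold changes went from -0.142 to -0.187 without small replicate 2 and reversed to 0.004 without small replicate 4; restricting it to called genes left no genes.

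Totals over all settings hide where calls failed. In every comparison, named genes lost the call more often with 1 library left out than in the other planned settings. Of 1792 values of named genes under alternatives, 1351 kept direction and call, 436 kept the direction but no longer passed, and 5 reversed. The last were DMO1 (2.03) and MRPL24 (0.34) in small against big colonies and RCN1 (0.98) in small colonies against unsorted particles, all with small replicates 1 and 3 added, and HHT2 with a 200 nt window (0.44 against batch culture, -0.68 in fixed against unfixed). Of 533 list values 373 kept direction and call, 158 no longer passed and 2 reversed by the direction of the test. The median changed sign in 2 more that no longer passed: oxidative phosphorylation in small colonies against unsorted particles without small replicate 4 (-0.34), and heat shock in fixed against unfixed without unsorted replicate 2 (0.13). The lowest totals, 1506960 tags in unsorted replicate 2, 1665301 in batch replicate 2 at Abs600 0.5 and 1873907 in small replicate 2, limit what the low-count genes can show.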

Other observations

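Fixed unsorted particles were compared with batch culture at Abs600 0.5 after the data had been seen. No gene passed the edgeR quasi-likelihood test, with 120 of 5528 at an unadjusted p under 0.05 where chance gives 276; DESeq2 called 1, limma-voom 0 and voom with sample quality weights 262 (91 higher, 171 lower). The edgeR count below chance leaves the test likely conservative here too. Lists lay to 1 side by the camera test. Of 19 mating genes 16 were negative, with a median log2 fold change of -1.0 (adjusted p = 0.0648 with an estimated correlation). Of 132 ribosomal protein genes 128 were negative, with a median of -0.62, while 72 of 83 ribosome biogenesis genes were positive, with a median of 0.53 (adjusted p = 0.298 and 0.316 with an estimated correlation). Of 39 genes of the G1/S transition 35 were negative, with a median of -0.74 (adjusted p = 0.109 with an estimated correlation). Medians were -1.01 for the phosphate regulon, -0.90 for the citric acid cycle, -0.84 for genes of the M/G1 transition and 0.53 for proteasome genes, of which 32 of 35 were positive (adjusted p = 0.298, 0.249, 0.298 and 0.298 with an estimated correlation). From mean log2 CPM these medians were -1.21, -1.01, -0.98 and 0.43. Without unsorted replicate 1 the first 2 were -0.77 and -0.601, without unsorted replicate 3 the last 2 were -0.63 and 0.28, and without unsorted replicate 2 the last was 0.75. The ribosome biogenesis median was 0.49, and 0.26 and 0.77 without batch replicates 1 and 2. All 13 lists called lost the call with an estimated correlation or fry.

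Some genes had more raw tags in small replicate 4, the library with the most tags, than in each other library. ALG9, a mannosyltransferase gene used as a reference, had 1635 tags there and 2 to 36 in the other 13 libraries. The mating type alpha genes STE3, MF(ALPHA)1 and MF(ALPHA)2 had 83, 137 and 63 tags there, against at most 6, 19 and 8 in another library. Scaled to library size, MF(ALPHA)2 was at 3.13 ± 4.42 CPM in small colonies (SD, n = 2) and 2.32 ± 4.01 CPM in fixed unsorted particles (SD, n = 3). Its order by raw tags therefore need not hold. MATALPHA2 and the silent locus gene HMLALPHA2 had 41 and 115 tags there and 0 in the other 13 libraries. Where near-identical copies share tags, such counts do not mark alpha cells. SAG1, the alpha-agglutinin gene, had 124 tags in small replicate 2 and 204 in small replicate 4, against 1 to 25 in the 12 others; SAG1 was at 80.04 CPM in small replicate 2 and 20.3 in replicate 4. The a-cell pheromone gene MFA2 had 8607 tags in the same library.

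The excluded libraries were compared as values. Excluded small replicate 1 correlated at 0.435 with small replicate 2, 0.463 with small replicate 4 and 0.528 with the mean of big colonies, and replicate 3 at 0.583, 0.474 and 0.625. They had tags on 2313 and 3662 genes.

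In the 16 libraries 6.79% to 26.5% of gene tags lay inside the ORF, the latter in unsorted replicate 2. Of these tags 62.0% to 94.5% preceded at least 6 A in the next 10 genome bases, against 19.9% to 28.6% of tags after the ORF.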
